A study of Mus musculus with 9 samples.

How the data were processed

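RNA from 9 mouse samples in 3 groups of 3 was measured by RNA sequencing. The groups, taken from the labels, were primary mouse embryonic fibroblasts (MEF), fibroblasts converted toward GABAergic interneurons (iGABA) and interneurons of the embryonic cortex (GAD67). Per the labels' protocols, total RNA was purified on spin columns made for small samples, and strand-marked libraries were built by the dUTP method. The labels record that the converted cells and the cortical interneurons were sorted for GFP before lysis, and that the fibroblasts were only detached with trypsin.

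The deposited table held whole-number read counts per gene for each library, not normalised. Per the submitters' processing notes, the authors used BWA 0.7.2, featureCounts and DESeq 1.10.1 with the mm10 genome. The role and order of these tools, the annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of a partner on the opposite strand cannot be told apart, so values of antisense genes and of genes that overlap another gene are uncertain. Genes with near-identical copies, such as Gapdh, Eno1, Pcna, Cox5b and the globin genes, are uncertain as well, since reads could have been split among copies or dropped. Most mitochondrial protein genes have close nuclear copies and carry the same limit.

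The table listed 37224 genes, each with an Ensembl identifier and a position, and no line that named no gene. Symbols came from GENCODE vM21 and were found for 35449 genes (95.2%), and 99.8% of those overlapped their vM21 position. In 6 cases a symbol named more than 1 gene. No count was recorded in any library for 11537 genes. Hoxd4, Slc18a3, Lhfpl3, Hbb-b1 and Hbb-b2, which are 5 members of the gene lists, had no entry under those names and were not analysed here.

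Library totals ran from 27501521 to 38975523 counts. A count of 0 in a library allows up to 3 counts, which corresponded to between 0.0717 and 0.110 CPM, which are counts scaled to the same total in each library. Intervals on ratios of low counts and floors at 0 counts cover counting error only. PCR copies without molecular identifiers are not independent molecules, so even that error may be larger. Intervals of the edgeR differences include the spread between libraries. The labels do not say whether replicates were separate cultures or animals, so p-values rest on the spread between these samples, which may be technical. For GAD67 cells the Xist levels given below argue against repeats of 1 RNA sample.

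Counts were analysed in R 4.3.3. Genes passed a low-count filter (edgeR filterByExpr, minimum count 10, minimum total 15), which left 18085 genes. Libraries were scaled by TMM, and normalised CPM use the scaled library sizes. Differences were tested with the quasi-likelihood test of edgeR 4.0.16, fitted to all 9 libraries together so that the 3 groups shared an estimate of the spread, with Benjamini-Hochberg adjustment over the tested genes. A gene rose, fell or was called when its adjusted p was under 0.05. Calls of at least 2-fold were counted separately. The shared biological coefficient of variation was 7.91%. Where a group had no count at all, a fold is given as a lower bound against 3 counts over the group, and where it had 1 to 3 counts a ratio with an exact 95% counting interval is given.

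There were 31 gene lists: reprogramming factors of the study, GABA synthesis and transport, GABA receptors and gephyrin, ventral forebrain and interneuron transcription factors, interneuron subtype markers, interneuron migration and guidance, pan-neuronal genes, presynaptic vesicle release, postsynaptic and glutamate receptors, voltage-gated ion channels, neuronal RNA-binding and splicing factors, proneural and Notch pathway genes, fibroblast and extracellular matrix, contractile and YAP target genes, trunk Hox genes, cell cycle, glutamatergic cortical neurons, other transmitter neurons, astrocytes and radial glia, oligodendrocyte lineage, microglia and other immune cells, endothelial cells, red blood cells, skeletal muscle, keratinocytes and other epithelium, interferon response, immediate early and dissociation genes, p53 and senescence genes, glycolysis, oxidative phosphorylation and cholesterol synthesis. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), which compares a list with the other genes, and adjusted over the lists. The same test with an estimated correlation and limma's fry, which asks whether the members move on balance in a single direction without comparing them with other genes, were run beside it.

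Genes at least 4-fold higher in GAD67 than in MEF cells were called interneuron genes, and genes at least 4-fold lower were called fibroblast genes. Each was sorted by whether iGABA cells had moved at least 2-fold from MEF, and whether the 95% interval of the difference from GAD67 lay within 2-fold. The position of an iGABA library is the median over those genes of its distance from the MEF mean as a percent of the distance between the MEF and GAD67 means. As the changes of iGABA and GAD67 cells share the 3 MEF libraries, their correlation and overlap are given beside 20 simulations with unchanged groups.

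The gene, list and class tests, the lists and the alternatives were chosen before the data were examined, as was the rule for named genes. That rule took the 6 largest increases and decreases per comparison with a mean of at least 50 CPM in the higher group and no overlap between libraries, the 5 reprogramming factors and 4 GABA genes, up to 2 members per direction of each list with a mean of at least 5 CPM and its most abundant member that was not called, and the 6 most abundant genes of each class. Genes named outside it are said to be so. Some genes that the rule selects are not reported here.

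The tests were tested on simulated counts with known changes. In each simulation 100 genes changed 2-fold and 100 changed 4-fold, as many up as down. In the real comparisons 80.6% to 86.9% of genes were called, so the simulated figures may not hold for them. For iGABA against MEF, 88 of 100 genes changed 2-fold and 99 of 100 changed 4-fold were recovered, with 14 false calls among 16344 genes. For GAD67 against MEF the figures were 87 and 100 of 100, with 13 false calls among 16314. For iGABA against GAD67 they were 87 and 98 of 100, with 18 false calls among 15966. The 95% intervals held the true change for 90% of genes at both folds for iGABA against MEF, for 97% (2-fold) and 96% (4-fold) for GAD67 against MEF, and for 97% and 91% for iGABA against GAD67, so some intervals, on which the sorting of genes as within 2-fold of GAD67 rests, were too narrow.

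Alternatives covered scaling by library size alone and by DESeq2 size factors, other low-count filters and none, DESeq2 1.42.0 and limma-voom in place of edgeR, a test against a 2-fold threshold (glmTreat), thinning to the smallest library, removing mitochondrial and the 10 most abundant genes, fitting only the libraries compared, other list tests, a 2-fold class definition, another prior count, and leaving out each library in turn. Division of the MEF libraries between the changes and the GABA list without Gad1 were added after the data were seen.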

Results

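Gene expression was measured in 3 kinds of mouse cells, with 3 libraries each. MEF cells were primary fibroblasts of mid-gestation embryos. Their labels also mention a later shift to neuronal inducing medium and do not say whether it preceded RNA extraction, so the medium behind every MEF value is uncertain. iGABA cells were fibroblasts after 14 days of conversion, of which 2 were spent in fibroblast medium before neuronal medium. The study is known to have used 5 transcription factors for this, Sox2, Dlx5 and Lhx6 among them. GAD67 cells were GFP-positive interneurons isolated from the cortex shortly before birth, with GFP reporting Gad1, the gene of the GABA-synthesising enzyme GAD67. Sorting for GFP set the Gad1 level in these cells, and in iGABA cells too if the same reporter was used, which the labels do not state, so Gad1 is given as a check of the labels and not as a difference found.

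Totals were 30979426, 35595196 and 38854863 counts in the MEF libraries, 35055639, 36799591 and 27501521 in iGABA, and 38975523, 37157528 and 35422435 in GAD67. Across genes, which are not independent replicates, log2 CPM of libraries of the same group correlated with Pearson r of 0.996 to 0.999. Mean r between groups was 0.863 for MEF and iGABA, 0.785 for MEF and GAD67, and 0.891 for iGABA and GAD67. No replicate pair agreed within counting noise, since the chi-square per gene was at least 2.49 within groups. The 10 most abundant genes took 11.7% ± 0.309 of counts in MEF, 6.29% ± 0.158 in iGABA and 3.24% ± 0.0239 in GAD67 libraries (SD, n = 3). Mitochondrially encoded genes took 0.973% ± 0.0828 of counts in MEF, 4.24% ± 0.207 in iGABA and 1.26% ± 0.130 in GAD67 libraries. These shares carry the limit on genes with close nuclear copies given above.

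To measure how converted cells differed from fibroblasts, iGABA was compared with MEF cells. The groups also differed in sorting, as iGABA cells were sorted for GFP and MEF cells were not, and whether they differed in medium is not clear from the labels. Most listed transcripts of neurons and of neuronal progenitors rose, collagen, matrix and contractile transcripts fell, and immune cell transcripts present in MEF cultures were almost gone. The proneural gene Insm1, a zinc-finger factor of newborn neurons, rose from 0.160 ± 0.0843 to 221 ± 2.81 CPM, and the fibronectin gene Fn1 fell from 6798 ± 802 to 25.6 ± 4.39 CPM (SD, n = 3). Trunk Hox genes, which mark position along the body, stayed on in the converted cells and most rose.

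In all, edgeR called 14806 of 18085 genes, 7618 higher and 7188 lower in iGABA cells, of which 1000 and 1236 changed at least 16-fold. Scaled by library size alone, the split was 9941 higher and 5283 lower. That scaling moved the median log2 fold change of all genes from 0.05 to 0.46, so small changes in this comparison hold relative to TMM scaling.

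All 5 reprogramming factors rose. Sox2 (ENSMUSG00000074637, mm10 chromosome 3, 34650005 to 34652461), a neural stem cell factor, went from 1.13 ± 0.217 to 1045 ± 92.8 CPM, a log2 fold change of 9.84. Dlx5 (ENSMUSG00000029755, chromosome 6, 6877805 to 6882085) rose from 1.87 ± 0.111 to 59.1 ± 0.611 CPM and Lhx6 (ENSMUSG00000026890, chromosome 2, 36081950 to 36105408) from 0.596 ± 0.158 to 75.5 ± 6.83 CPM, both being factors of ventral forebrain neurons. Counts per gene do not separate transcripts of delivered copies from those of the cell's own genes. The study chose this list for these cells, so its camera call (limma, adjusted p = 0.000817, and adjusted p = 0.0665 with an estimated correlation) is not independent evidence.

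The 5 genes of GABA synthesis and transport rose as well, to unequal levels. Gad1 (ENSMUSG00000070880, chromosome 2, 70553072 to 70602014) went from 0.544 ± 0.0713 to 405 ± 8.21 CPM. Gad2 (ENSMUSG00000026787, chromosome 2, 22622205 to 22693874), which encodes the second GABA-synthesising enzyme, reached 9.45 ± 1.05 CPM. The vesicular GABA transporter Slc32a1 (ENSMUSG00000037771, chromosome 2, 158610767 to 158615748) reached 2.825 ± 0.433 CPM. The list was called by limma's camera at adjusted p = 0.00326, and had adjusted p = 0.0705 with an estimated correlation. Without Gad1, left out after the data were seen because of the sort, limma's camera gave adjusted p = 0.0149, and adjusted p = 0.190 with an estimated correlation. Of 14 measured genes of GABA receptors and their anchor gephyrin, 7 rose, 5 fell and 2 did not pass (limma's camera, adjusted p = 0.769). Gabbr2, a GABA-B receptor subunit, rose from 0.222 ± 0.139 to 9.02 ± 0.406 CPM.

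**Figure D1:**
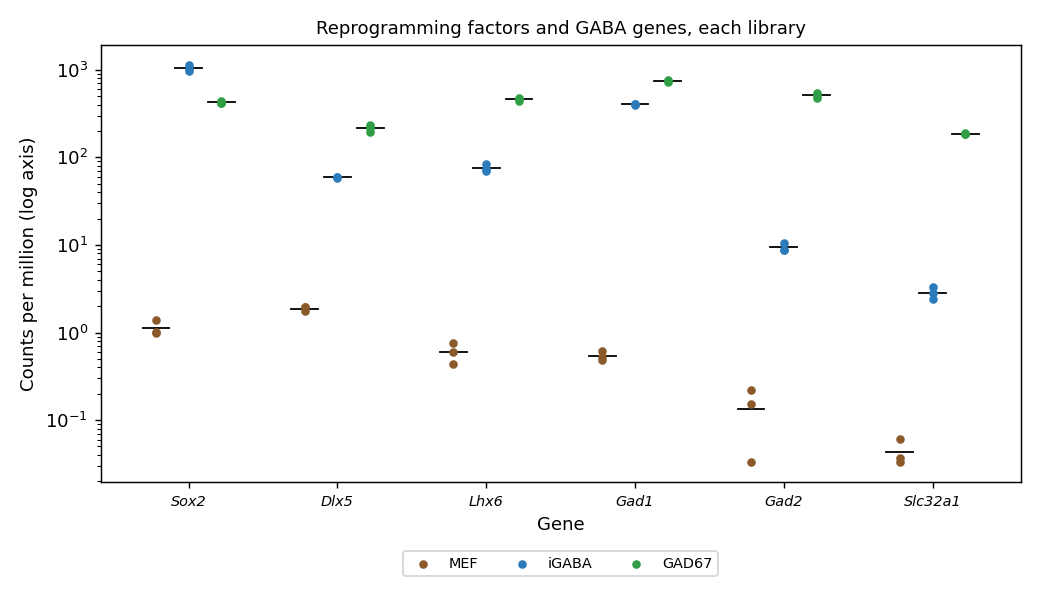
CPM of 3 reprogramming factors and 3 GABA genes in each library on a log axis, with points for libraries and bars for group means (n = 3). Sox2 stands at 1045 CPM in iGABA and 425 in GAD67 libraries, while Slc32a1 stands at 2.825 and 186 CPM.

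Neuronal lists rose broadly. Among pan-neuronal genes, 25 of 27 rose, 1 fell and 1 did not pass (limma's camera, adjusted p = 1.26e-07). The microtubule regulator Stmn3 rose from 0.112 ± 0.0302 to 119 ± 7.70 CPM, the neuronal tubulin Tubb3 from 4.29 ± 0.280 to 204 ± 4.31 CPM, and the related regulator Stmn2 fell from 33.5 ± 0.758 to 23.3 ± 3.13 CPM. The Stmn2 call was lost with scaling by library size alone (edgeR, adjusted p = 0.234). All 20 measured proneural and Notch pathway genes rose (limma's camera, adjusted p = 1.86e-07), among them the Notch ligand Dll3, from 0.153 ± 0.0255 to 107 ± 4.26 CPM. Presynaptic vesicle release genes rose in 24 of 26 cases, with 1 fall and 1 that did not pass (limma's camera, adjusted p = 1.86e-07, and adjusted p = 0.0665 with an estimated correlation). The synaptic vesicle protein gene Syp went from 0.475 ± 0.0431 to 217 ± 26.0 CPM. Voltage-gated ion channels gave 17 rises, 5 falls and 1 that did not pass of 23 (limma's camera, adjusted p = 0.00546, and adjusted p = 0.0977 with an estimated correlation), led by the potassium channel Kcnt1, from 0.639 ± 0.0974 to 318 ± 5.14 CPM. This call was lost with scaling by library size alone, where limma's camera gave adjusted p = 0.0593 (alternatives from 4.61e-09 to 0.0977). Neuronal RNA-binding and splicing factors gave 12 rises, 1 fall and 1 that did not pass of 14 (limma's camera, adjusted p = 0.000181, and adjusted p = 0.0705 with an estimated correlation). Postsynaptic and glutamate receptor genes split into 15 that rose and 7 that fell (limma's camera, adjusted p = 0.0823), with the NMDA receptor subunit Grin1 up from 1.35 ± 0.256 to 24.99 ± 1.82 CPM and the AMPA receptor subunit Gria3 down from 176 ± 8.69 to 14.3 ± 0.851 CPM.

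Interneuron-specific lists moved both ways, and none of the 3 was called by camera, which compares them with other genes. By limma's fry, which does not, ventral factors (adjusted p = 2.73e-08) and subtype markers (adjusted p = 1.77e-07) were called up and migration genes (adjusted p = 0.0154) down. Ventral forebrain and interneuron transcription factors gave 11 rises, 8 falls and 6 that did not pass of 25 (limma's camera, adjusted p = 0.266). Gsx2 (ENSMUSG00000035946, chromosome 5, 75075464 to 75077893), a progenitor factor of the ventral forebrain, stood at 67.8 ± 5.91 CPM against no count in 3 MEF libraries, at least 2036-fold higher, and its relative Gsx1 rose from 0.0796 ± 0.0431 to 128 ± 9.31 CPM. Zeb2, needed for cortical interneuron fate, fell from 84.4 ± 2.02 to 10.4 ± 1.64 CPM. Interneuron subtype markers gave 10 rises, 6 falls and 2 that did not pass of 18 (limma's camera, adjusted p = 0.397), with the potassium channel Kcnc1 up from 0.751 ± 0.259 to 501 ± 21.5 CPM and the serotonin receptor Htr3a up from 1.101 ± 0.0723 to 355 ± 6.16 CPM. Migration and guidance genes gave 6 rises, 9 falls and 2 that did not pass of 17 (limma's camera, adjusted p = 0.622), where the median log2 fold change was -0.16 and the mean 0.06.

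Fibroblast transcripts fell together. All 36 fibroblast and extracellular matrix genes fell, with a median log2 fold change of -6.24 (limma's camera, adjusted p = 2.77e-12, and adjusted p = 0.0876 with an estimated correlation). The collagen gene Col1a1 went from 38876 ± 2112 to 249.9 ± 42.7 CPM. All 20 contractile and YAP target genes fell (limma's camera, adjusted p = 1.02e-08, and adjusted p = 0.0705 with an estimated correlation), among them smooth muscle actin Acta2, from 4710.3 ± 255 to 6.54 ± 1.72 CPM. Skeletal muscle genes, present at low level in the unsorted MEF cultures, fell in 18 of 19 cases and 1 did not pass (limma's camera, adjusted p = 4.78e-05, and adjusted p = 0.0876 with an estimated correlation). Cell cycle genes gave 24 falls, 5 rises and 1 that did not pass of 30 (limma's camera, adjusted p = 0.0164, and adjusted p = 0.750 with an estimated correlation). The mitotic kinase Cdk1 went from 77.7 ± 4.79 to 17.4 ± 6.44 CPM. Of the 24 trunk Hox genes, 19 rose, 3 fell and 2 did not pass (limma's camera, adjusted p = 0.0156, and adjusted p = 0.328 with an estimated correlation). Hoxb5 rose from 3.21 ± 0.106 to 26.2 ± 0.517 CPM and Hoxa10 fell from 68.8 ± 1.097 to 18.4 ± 0.260 CPM. Hox transcripts overlap others on both strands, which leaves single Hox levels uncertain.

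Among other cell types, compared here between GFP-sorted iGABA and unsorted MEF samples, microglia and other immune cell markers fell in 16 of 16 cases (limma's camera, adjusted p = 3.99e-07). C1qa, a complement gene of macrophages, stood at 33.1 ± 1.70 CPM in MEF and at no count in iGABA libraries, at least 1260.3-fold lower. Endothelial markers gave 7 falls, 1 rise and 5 that did not pass of 13 (limma's camera, adjusted p = 0.118). None of the 5 red blood cell genes passed in edgeR, and 0 had an unadjusted p under 0.05 (limma's camera, adjusted p = 0.975). Each had at most 3 counts over the 3 libraries of either group, too few for a difference to be detected. Glutamatergic cortical neuron genes gave 7 rises, 4 falls and 6 that did not pass of 17 (limma's camera, adjusted p = 0.534), with a median log2 fold change of 1.53, or 0.53 with genes at 0 set to their bound. Eomes, a factor of cortical intermediate progenitors, rose from 1.01 ± 0.183 to 273 ± 5.85 CPM. Other transmitter neuron genes gave 3 rises, 1 fall and 2 that did not pass of 6 (limma's camera, adjusted p = 0.900). Astrocyte and radial glia genes gave 6 rises, 8 falls and 2 that did not pass of 16 (limma's camera, adjusted p = 0.519), and oligodendrocyte genes 5 rises, 2 falls and 2 that did not pass of 9 (limma's camera, adjusted p = 0.160). Keratinocyte and other epithelial genes gave 3 rises, 4 falls and 3 that did not pass of 10 (limma's camera, adjusted p = 0.793), where the median log2 fold change of 0.38 differed in sign from the mean of -0.85.

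Of the lists on cell state, interferon response genes gave 17 falls, 2 rises and 1 that did not pass of 20 (limma's camera, adjusted p = 0.000264, and adjusted p = 0.0705 with an estimated correlation). p53 and senescence genes gave 11 falls, 3 rises and 1 that did not pass of 15 (limma's camera, adjusted p = 0.0434, and adjusted p = 0.116 with an estimated correlation). That call was lost without iGABA replicate 6, where limma's camera gave adjusted p = 0.0546, and alternatives ranged from 7.05e-09 to 0.122, the last with library size alone, where the median log2 fold change was 0.07. The cell cycle inhibitor Cdkn1a rose from 339 ± 14.4 to 534 ± 18.1 CPM. Immediate early and dissociation genes gave 4 rises, 11 falls and 5 that did not pass of 20 (limma's camera, adjusted p = 0.338). Glycolysis genes gave 8 rises, 7 falls and 2 that did not pass of 17 (limma's camera, adjusted p = 0.975), with a median log2 fold change of -0.03 and a camera direction of up. Oxidative phosphorylation gave 10 rises, 7 falls and 10 that did not pass of 27 (limma's camera, adjusted p = 0.747), and cholesterol synthesis 6 rises, 14 falls and 2 that did not pass of 22 (limma's camera, adjusted p = 0.245). Adjusted over the list alone, the counts of all lists were those given, except that 6 and not 7 glutamatergic genes rose. In this comparison 8 lists were called higher and 7 lower, and pan-neuronal, proneural and microglia genes kept their call with an estimated correlation, each at an adjusted p of 0.0282 in limma's camera.

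The 6 largest increases by the fixed rule were Gsx2, Ntsr2, Prlhr, Cidea, Pkd2l1 and Prmt8. The neurotensin receptor Ntsr2 reached 123 ± 0.268 CPM against 1 count in MEF libraries, a ratio of 11150.2 (95% interval 2001 to 440441). Pkd2l1 (ENSMUSG00000037578, chromosome 19, 44147637 to 44192442), an ion channel of neurons that contact the cerebrospinal fluid, went from 0.235 ± 0.141 to 549.6 ± 23.3 CPM. The 6 largest decreases were Flt1, Lyz2, Mpeg1, Hmga2, Mrc1 and Acta2, of which Lyz2, Mpeg1 and Mrc1 are macrophage genes. Hmga2, a chromatin protein of embryonic cells, fell from 185 ± 6.72 to 0.194 ± 0.0230 CPM.

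The target state was measured by comparing GAD67 with MEF cells. These groups also differed in sorting, and MEF cells were cultured while GAD67 cells were isolated from cortex. Cortical interneurons held most listed GABA genes, ventral forebrain factors, synaptic genes and migration genes at least 2-fold above the fibroblast level. Some members of these lists went the other way. Hox genes stood near 0 in the interneurons, and fibroblast matrix genes stood far below their MEF level, with Col1a1 still at 81.5 CPM. Doublecortin (Dcx), a protein of migrating neurons, stood at 3215 ± 156 CPM against 15.1 ± 1.06 in MEF cells, and the collagen-binding protein gene Lum at 0.0624 ± 0.0151 against 419 ± 26.9 CPM (SD, n = 3).

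The edgeR test called 15720 genes, 7801 higher and 7919 lower in GAD67 cells, with 5150 and 5722 of at least 2-fold and 1267 and 2205 of at least 16-fold. All 5 reprogramming factors stood higher than in MEF cells, with Sox2 at 425 ± 15.7, Lhx6 at 464 ± 18.7 and Dlx5 at 215 ± 18.8 CPM (limma's camera, adjusted p = 0.00181). All 5 GABA synthesis and transport genes were higher (limma's camera, adjusted p = 0.00181), with Gad2 at 514 ± 34.4 and Slc32a1 at 186 ± 3.50 CPM, and Gad1, whose level the sort set, at 745 ± 25.2 CPM. Without Gad1 limma's camera gave adjusted p = 0.00606, and adjusted p = 0.112 with an estimated correlation. GABA receptor and gephyrin genes were higher in 12 and lower in 2 of 14 cases (limma's camera, adjusted p = 0.00209, and adjusted p = 0.109 with an estimated correlation).

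Ventral forebrain and interneuron transcription factors were higher in 24 of 25 cases and 1, Gsx1, did not pass (limma's camera, adjusted p = 8.72e-08). Six3, a forebrain factor, stood at 159 ± 7.40 CPM against 0.0521 ± 0.0468, and Nkx2-1, the factor of the medial ganglionic eminence where many cortical interneurons arise, at 18.53 ± 7.13 CPM against no count, at least 565.9-fold higher. Subtype markers were higher in 13, lower in 3 and did not pass in 2 of 18 cases (limma's camera, adjusted p = 0.0142, and adjusted p = 0.0740 with an estimated correlation), with a median log2 fold change of 3.12, or 2.73 with genes at 0 set to their bound. The neuropeptide gene Sst varied among the GAD67 libraries, at 28.0, 34.9 and 10.2 CPM. Migration and guidance genes were higher in 14 and lower in 3 of 17 cases (limma's camera, adjusted p = 0.000878), with the neuregulin receptor Erbb4 at 588 ± 73.1 CPM against 2.02 ± 0.0298.

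Pan-neuronal genes were higher in 26 and lower in 1 of 27 cases (limma's camera, adjusted p = 1.02e-08), presynaptic genes higher in 23, lower in 1 and not passing in 2 of 26 (adjusted p = 4.09e-07), and postsynaptic genes higher in 21 and lower in 1 of 22 (adjusted p = 4.91e-06). Elavl3, a neuronal RNA-binding protein, stood at 1085 ± 18.1 CPM against 0.347 ± 0.0843. Ion channels were higher in 20, lower in 2 and not passing in 1 of 23 cases (limma's camera, adjusted p = 2.22e-05). All 14 neuronal RNA-binding and splicing factors were higher (limma's camera, adjusted p = 1.0999e-06), and proneural genes were higher in 18, lower in 1 and not passing in 1 of 20 cases (limma's camera, adjusted p = 3.51e-06).

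All 36 fibroblast and matrix genes were lower, with a median log2 fold change of -8.55 (limma's camera, adjusted p = 1.05e-11, and adjusted p = 0.0588 with an estimated correlation), as were all 20 contractile genes (limma's camera, adjusted p = 6.22e-08) and all 24 Hox genes, with a median of -9.14, or -9.06 with genes at 0 set to their bound (limma's camera, adjusted p = 1.51e-08). Cell cycle genes were lower in 25, higher in 4 and not passing in 1 of 30 cases (limma's camera, adjusted p = 0.00246, and adjusted p = 0.533 with an estimated correlation). All 20 interferon genes (limma's camera, adjusted p = 4.09e-07) and all 15 p53 and senescence genes (adjusted p = 1.42e-05) were lower. Immediate early genes were lower in 13, higher in 5 and not passing in 2 of 20 cases (limma's camera, adjusted p = 0.0228, and adjusted p = 0.495 with an estimated correlation). That call was lost without GAD67 replicate 9 (limma's camera, adjusted p = 0.0609, alternatives from 1.07e-06 to 0.495), and Fos, an activity-regulated factor, read 125, 179.7 and 33.8 CPM in the GAD67 libraries. Metabolic lists were lower as well. Glycolysis genes were lower in 12, higher in 2 and not passing in 3 of 17 cases (limma's camera, adjusted p = 0.00559, and adjusted p = 0.280 with an estimated correlation), and cholesterol synthesis genes lower in 19 and higher in 3 of 22 (adjusted p = 0.00182, and adjusted p = 0.288 with an estimated correlation). Oxidative phosphorylation genes were lower in 18, higher in 3 and not passing in 6 of 27 cases (limma's camera, adjusted p = 0.0367, and adjusted p = 0.631 with an estimated correlation). That last call was lost without MEF replicate 3, GAD67 replicate 7 or GAD67 replicate 9 (limma's camera, adjusted p = 0.0629, 0.0531 and 0.0729), with alternatives from 0.000468 to 0.631.

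Listed markers of other cell types were measurable in the GAD67 libraries. Whether they came from other cells or from the sorted interneurons was not tested. All 5 red blood cell genes were higher than in MEF cells (limma's camera, adjusted p = 0.0126, and adjusted p = 0.280 with an estimated correlation), with the globin gene Hbb-bs at 18.7 ± 8.52 CPM. Endothelial markers were higher in 6, lower in 4 and not passing in 3 of 13 cases (limma's camera, adjusted p = 0.692), with the tight junction gene Cldn5 at 7.03 ± 3.75 CPM against no count. Glutamatergic cortical neuron genes were higher in 14 and lower in 3 of 17 cases (limma's camera, adjusted p = 0.0142, and adjusted p = 0.107 with an estimated correlation), with the cortical pyramidal neuron factor Neurod6 at 14.3 ± 6.20 CPM against no count. Other transmitter neuron genes were higher in 3 and lower in 3 of 6 cases (limma's camera, adjusted p = 0.770). Astrocyte and radial glia genes were higher in 7 and lower in 9 of 16 cases (limma's camera, adjusted p = 0.608), where the median log2 fold change was -0.48 and the mean 0.01. Oligodendrocyte genes were higher in 6, lower in 2 and not passing in 1 of 9 cases (limma's camera, adjusted p = 0.196).

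The reverse held for markers carried by MEF cultures. Microglia and immune markers were lower in 15 of 16 cases and 1 did not pass (limma's camera, adjusted p = 1.51e-05), with the macrophage lysozyme gene Lyz2 at 225 ± 12.6 CPM in MEF and 0.0701 ± 0.0812 in GAD67 libraries. All 19 skeletal muscle genes were lower (limma's camera, adjusted p = 2.85e-05, and adjusted p = 0.0588 with an estimated correlation). Keratinocyte and epithelial genes were lower in 8, higher in 1 and not passing in 1 of 10 cases (limma's camera, adjusted p = 0.0197, and adjusted p = 0.0740 with an estimated correlation), with a median log2 fold change of -6.53, or -4.60 with genes at 0 set to their bound. Adjusted over the list alone, all of these counts were unchanged. Of 14 lists called higher and 13 called lower, 10 and 5 kept their call with an estimated correlation, and the full lists that lost it are the ones given with that p.

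How far the converted cells were from interneurons was measured by comparing iGABA with GAD67 cells. iGABA cells came from 14 days of conversion in culture and GAD67 cells from cortical tissue. Conversion and culture therefore cannot be told apart in this comparison. Of the delivered factors, Sox2 stood above the interneuron level and Dlx5 and Lhx6 below it. GABA genes, most GABA receptors, most ventral forebrain factors and most synaptic receptor genes stood below, Gad2 and Slc32a1 by more than 50-fold. Trunk Hox genes, near 0 in interneurons, stood higher by a median log2 fold change of 10.08, and p53 genes were higher too. Fibroblast and glycolysis genes were higher by limma's camera with the preset correlation, with adjusted p = 0.207 and adjusted p = 0.185 with an estimated correlation.

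The edgeR test called 14569 genes, 7461 higher and 7108 lower in iGABA cells, with 4807 and 3626 of at least 2-fold and 1279 and 666 of at least 16-fold. The log2 fold change of Sox2 against GAD67 was 1.30, while Lhx6 stood at -2.62 and Dlx5 at -1.86. The factor list as a whole, 3 members higher and 2 lower, was not called (limma's camera, adjusted p = 0.730). All 5 GABA synthesis and transport genes were lower (limma's camera, adjusted p = 0.00802, and adjusted p = 0.107 with an estimated correlation), with log2 fold changes of -6.02 for Slc32a1, -5.76 for Gad2 and -0.88 for Gad1. Without Gad1 limma's camera gave adjusted p = 0.0143, and adjusted p = 0.200 with an estimated correlation. GABA receptor and gephyrin genes were lower in 12 cases and did not pass in 2 of 14 (limma's camera, adjusted p = 0.000618, and adjusted p = 0.148 with an estimated correlation), with the GABA-A subunit Gabrb2 at 0.408 ± 0.0855 CPM against 33.0 ± 6.57.

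Ventral forebrain and interneuron transcription factors were lower in 23 of 25 cases and higher in 2, the progenitor factors Gsx1 and Gsx2 (limma's camera, adjusted p = 1.59e-06). Sp9, a factor of postmitotic interneurons, stood at 0.141 ± 0.0600 CPM against 459 ± 21.3, Sp8 at 0.128 ± 0.0581 against 213 ± 21.7, and Nr2e1 at no count against 24.4 ± 4.10, at least 924-fold lower. Dlx1, which acts with Dlx5 in interneuron development, stood at 77.4 ± 3.92 CPM against 1482 in GAD67 cells. Subtype markers were lower in 12, higher in 5 and not passing in 1 of 18 cases (limma's camera, adjusted p = 0.118). Sst stood at 2 counts over 3 iGABA libraries, a ratio of 1411 (95% interval 390.2 to 11657) in favour of GAD67 cells, while Htr3a was higher in iGABA, at 355 ± 6.16 against 100.9 ± 7.19 CPM. Migration and guidance genes were lower in 13, higher in 2 and not passing in 2 of 17 cases (limma's camera, adjusted p = 0.000158, and adjusted p = 0.0542 with an estimated correlation), with Erbb4 at 1.04 ± 0.204 against 588 ± 73.1 CPM.

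Pan-neuronal genes were lower in 23 and higher in 4 of 27 cases (limma's camera, adjusted p = 1.42e-05). Rtn1, a membrane protein of neurons, stood at 13.1 ± 1.11 against 842 ± 36.7 CPM, while the neuronal enolase Eno2 was higher, at 254 ± 15.9 against 35.9 ± 5.45 CPM. Presynaptic genes were lower in 15, higher in 8 and not passing in 3 of 26 cases (limma's camera, adjusted p = 0.138). The vesicle fusion regulator Cplx2 was higher in iGABA, at 1043 ± 13.4 against 269 ± 48.7 CPM, and the active zone protein gene Rims1 lower, at 0.514 ± 0.101 against 43.1 ± 5.26 CPM. Postsynaptic genes were lower in 20 and higher in 2 of 22 cases (limma's camera, adjusted p = 5.94e-05). Ion channels were lower in 17 and higher in 6 of 23 (limma's camera, adjusted p = 0.0233, and adjusted p = 0.185 with an estimated correlation). RNA-binding and splicing factors were lower in 13 and higher in 1 of 14 (limma's camera, adjusted p = 0.000184, and adjusted p = 0.0838 with an estimated correlation), with Ptbp2, a splicing regulator of developing neurons, at 20.7 ± 0.479 against 430.2 ± 30.4 CPM. Proneural and Notch genes split into 11 higher and 9 lower (limma's camera, adjusted p = 0.978). There the median log2 fold change of 0.67 and camera pointed up, while the mean of -0.19 and fry pointed down. Dll3 stood at 107 ± 4.26 against 8.94 ± 0.560 CPM and Scrt2, a factor of newborn neurons, at 10.1 ± 0.295 against 189.5 ± 14.3 CPM.

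**Figure D2:**
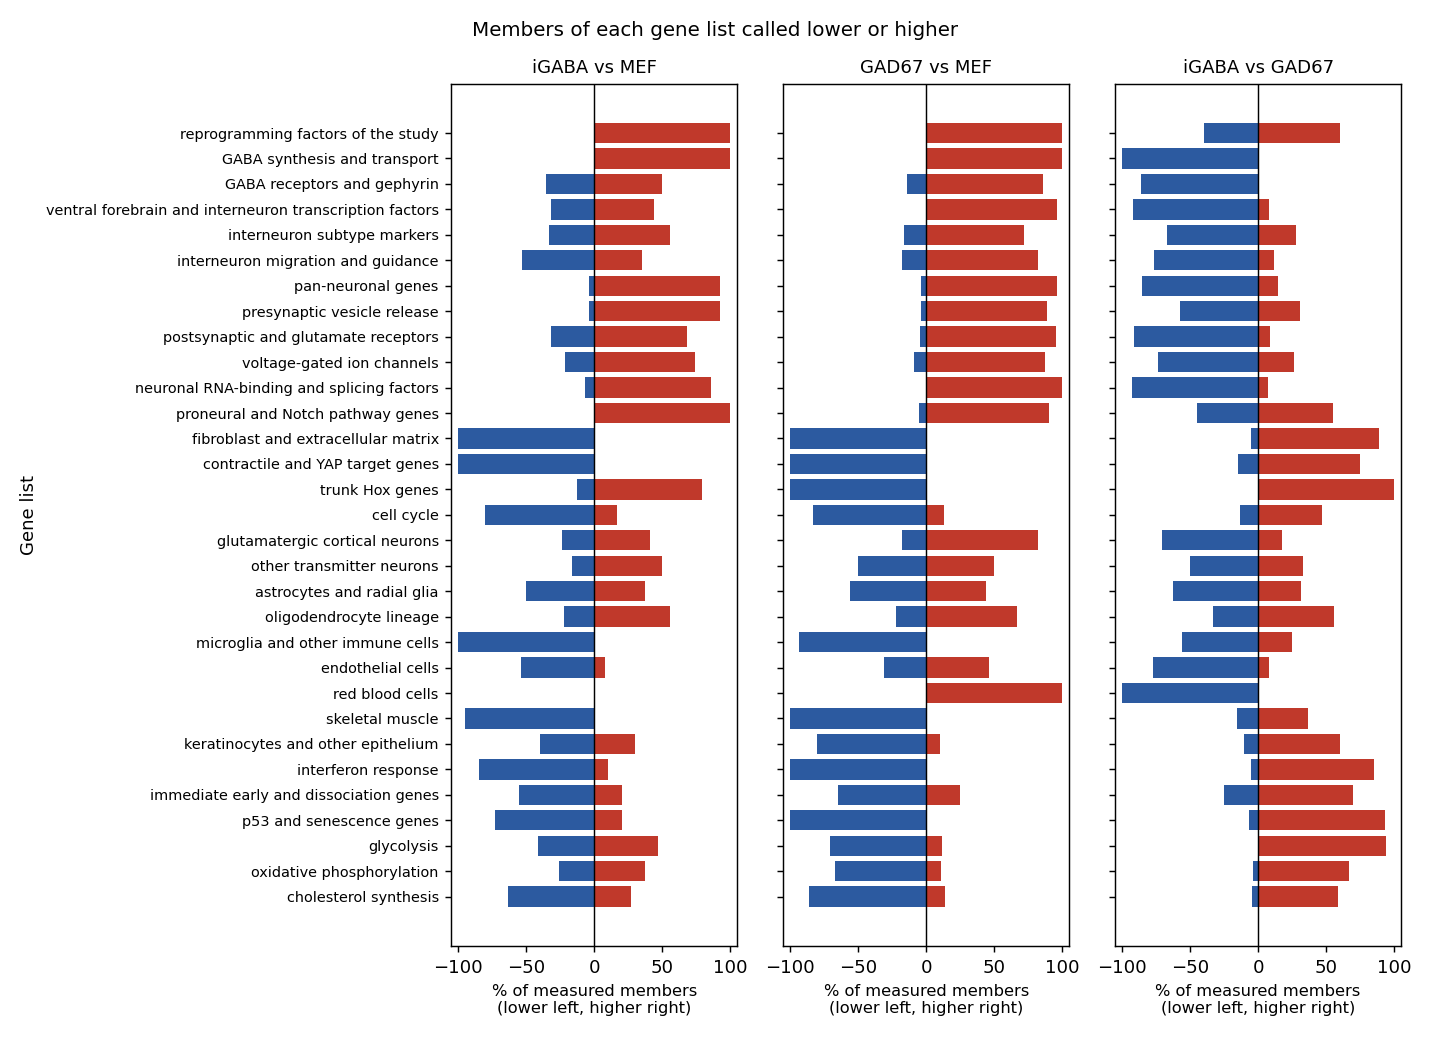
Percent of the measured members of each of 31 gene lists called lower (blue, to the left) and higher (red, to the right) in each comparison by edgeR. In iGABA against GAD67 cells, all 24 trunk Hox genes were higher and all 5 GABA synthesis and transport genes were lower.

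All 24 trunk Hox genes were higher in iGABA than in GAD67 cells (limma's camera, adjusted p = 1.94e-10), with a median log2 fold change of 10.08, or 10.05 with genes at 0 set to their bound. Hoxb5 stood at 26.2 ± 0.517 CPM against no count in GAD67 libraries, at least 977-fold higher. Hoxb7 stood at 58.0 ± 2.29 CPM against 3 counts, a ratio of 2171 (95% interval 742.4 to 10528). Fibroblast and matrix genes were higher in 32, lower in 2 and not passing in 2 of 36 cases (limma's camera, adjusted p = 3.52e-06, and adjusted p = 0.207 with an estimated correlation), with a median log2 fold change of 2.62. The hyaluronan receptor Cd44 stood at 231 ± 14.1 CPM against 0.338 ± 0.0759. Contractile genes were higher in 15, lower in 3 and not passing in 2 of 20 (limma's camera, adjusted p = 0.00802, and adjusted p = 0.286 with an estimated correlation).

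**Figure D3:**
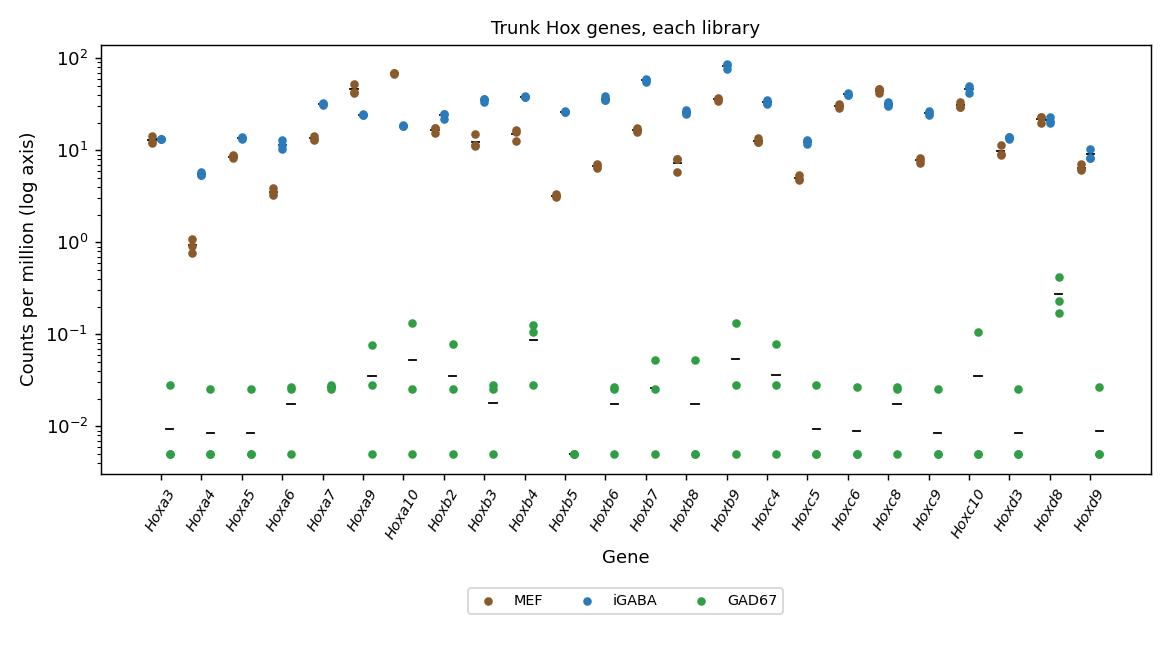
CPM of the 24 measured trunk Hox genes in each library on a log axis, with points for libraries and short bars for group means (n = 3), and libraries with no count drawn on the bottom line. iGABA libraries lie near or above MEF libraries for most genes, such as Hoxb5 at 26.2 and 3.21 CPM, and all GAD67 libraries lie far below both.

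Several lists on cell state were higher in iGABA than in GAD67 cells. All 20 interferon and all 15 p53 and senescence genes were also higher in MEF than in GAD67 cells. These differences therefore cannot be assigned to conversion rather than to culture. p53 and senescence genes were higher in 14 and lower in 1 of 15 cases (limma's camera, adjusted p = 0.000154), with a median log2 fold change of 3.98, or 2.95 with genes at 0 set to their bound. Cdkn1a stood at 534 ± 18.1 against 6.59 ± 1.93 CPM. Interferon genes were higher in 17, lower in 1 and not passing in 2 of 20 (limma's camera, adjusted p = 7.17e-05, and adjusted p = 0.0542 with an estimated correlation). Glycolysis genes were higher in 16 of 17 and 1 did not pass (limma's camera, adjusted p = 6.96e-05, and adjusted p = 0.185 with an estimated correlation), with the enzyme Aldoa at 945.5 ± 13.6 against 77.9 ± 4.27 CPM. Oxidative phosphorylation genes were higher in 18, lower in 1 and not passing in 8 of 27 (limma's camera, adjusted p = 0.0149, and adjusted p = 0.607 with an estimated correlation), and cholesterol synthesis genes higher in 13, lower in 1 and not passing in 8 of 22 (adjusted p = 0.00802, and adjusted p = 0.443 with an estimated correlation). Immediate early genes were higher in 14, lower in 5 and not passing in 1 of 20 (limma's camera, adjusted p = 0.0149, and adjusted p = 0.512 with an estimated correlation). Cell cycle genes were higher in 14, or 13 adjusted over the list alone, lower in 4 and not passing in 12 of 30 (limma's camera, adjusted p = 0.330). Without iGABA replicate 5 the cell cycle list was called higher (limma's camera, adjusted p = 0.0201, alternatives from 0.0175 to 0.819). The proliferation marker Mki67 read 83.1 ± 27.9 CPM in iGABA and 73.3 ± 9.65 in GAD67 libraries and did not pass. Without iGABA replicate 5 it was called higher in iGABA (edgeR, adjusted p = 0.00964).

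Markers of other cell types differed in both directions. Red blood cell genes were lower in 5 of 5 cases (limma's camera, adjusted p = 0.00739, and adjusted p = 0.286 with an estimated correlation), endothelial genes lower in 10, higher in 1 and not passing in 2 of 13 (adjusted p = 0.0233, adjusted p = 0.573 with an estimated correlation, and lost with 4 other settings), and glutamatergic genes lower in 12, higher in 3 and not passing in 2 of 17 (adjusted p = 0.0149, and adjusted p = 0.171 with an estimated correlation). Eomes was higher in iGABA, at 273 ± 5.85 against 6.98 ± 2.13 CPM. Keratinocyte and epithelial genes were higher in 6, lower in 1 and not passing in 3 of 10 (limma's camera, adjusted p = 0.0471, and adjusted p = 0.171 with an estimated correlation). That call was lost without MEF replicate 2, without any of the 3 iGABA replicates, and without GAD67 replicate 8 or 9, at adjusted p from 0.0524 to 0.123 in limma's camera, within a range over all alternatives of 2.49e-07 to 0.331. Microglia genes were lower in 9, or 10 adjusted over the list alone, higher in 4 and not passing in 3 of 16 (limma's camera, adjusted p = 0.330). Skeletal muscle genes were higher in 7, or 5 adjusted over the list alone, lower in 3 and not passing in 9 of 19 (limma's camera, adjusted p = 0.530). Other transmitter genes were higher in 2, lower in 3 and not passing in 1 of 6 (limma's camera, adjusted p = 0.673). Astrocyte and radial glia genes were higher in 5, lower in 10 and not passing in 1 of 16 (limma's camera, adjusted p = 0.435), with Pax6 at 0.0401 ± 0.0496 against 57.1 ± 3.27 CPM, and fry pointed up where camera and the median of -1.37 pointed down. Oligodendrocyte genes were higher in 5, lower in 3 and not passing in 1 of 9 (limma's camera, adjusted p = 0.570), where the median log2 fold change of 0.26 and the mean of -0.32 differed in sign. Adjusted over the list alone, the other counts of this comparison were unchanged. Of 10 lists called higher and 11 lower, Hox genes (adjusted p = 0.0467 in limma's camera) and p53 genes kept their call as higher with an estimated correlation, and ventral factors, pan-neuronal and postsynaptic genes as lower (each adjusted p = 0.0440, p53 genes included).

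The largest differences by the fixed rule included Hoxb7, Hoxb9, Pkd2l1, Sowahb and Gsx1 above, and Six3os1, Six3, Sp9, Adarb2, Sp8 and Pou3f4 below the interneuron level. Pkd2l1 stood at 549.6 ± 23.3 CPM against 0.480 ± 0.319. Six3os1 lies beside Six3 on the opposite strand, so reads of this pair cannot be told apart here.

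Genes were then sorted by how far iGABA cells had moved. The classes rest on the GAD67 and MEF libraries as sampled, so interneuron genes included 5 red blood cell, 6 endothelial and 12 glutamatergic markers, and fibroblast genes 15 immune and 16 skeletal muscle markers. Of 2843 interneuron genes, 1937 (68.1%) rose at least 2-fold from MEF, 768 did not move that far and 138 fell at least 2-fold. Among those that rose, 455 lay within 2-fold of the GAD67 level, 881 at least 2-fold short, 302 at least 2-fold past it and 299 in none of these. Nnat, an imprinted neuronal membrane gene, reached 2981 ± 170.2 CPM against 3046 in GAD67 cells, from 12.5 ± 0.357 in MEF. Dcx stayed short, at 82.5 ± 4.66 against 3215 CPM, and the adhesion molecule Cntn2 passed the interneuron level, at 1307 ± 146 against 149 CPM. The axonal protein gene Basp1 fell, from 238 ± 10.4 to 20.8 ± 1.08 CPM, away from its GAD67 level of 973 CPM.

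Of 3812 fibroblast genes, 2625 (68.9%) fell at least 2-fold, 888 did not move that far and 299 rose at least 2-fold. Among those that fell, 319 lay within 2-fold of the GAD67 level, 1382 remained at least 2-fold above it, 236 lay at least 2-fold below it and 688 in none of these. Col1a2 fell from 24134 ± 1251 to 214 ± 72.8 CPM but stood above its GAD67 level of 9.53 CPM. The lysosomal cholesterol carrier Npc2 stayed high, at 952 ± 13.2 CPM against 96.0 in GAD67 cells. Dlk1 (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336), an imprinted gene that encodes a Notch pathway ligand, rose from 1420.1 ± 69.1 to 6047 ± 102 CPM, away from 15.1 CPM. Among the lists, 21 of 25 pan-neuronal interneuron genes and 8 of 20 ventral transcription factors had risen, and 34 of 36 fibroblast and matrix genes but 1 of 24 Hox genes had fallen at least 2-fold.

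Over the interneuron genes, the iGABA libraries lay at 54.9%, 55.4% and 54.0% of the log2 distance from MEF to GAD67 (mean 54.7% ± 0.713, SD, n = 3), and over the fibroblast genes at 51.8%, 54.1% and 50.8% (mean 52.3% ± 1.72). The positions were not tested, and they use the MEF libraries that also chose the genes.

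**Figure D4:**
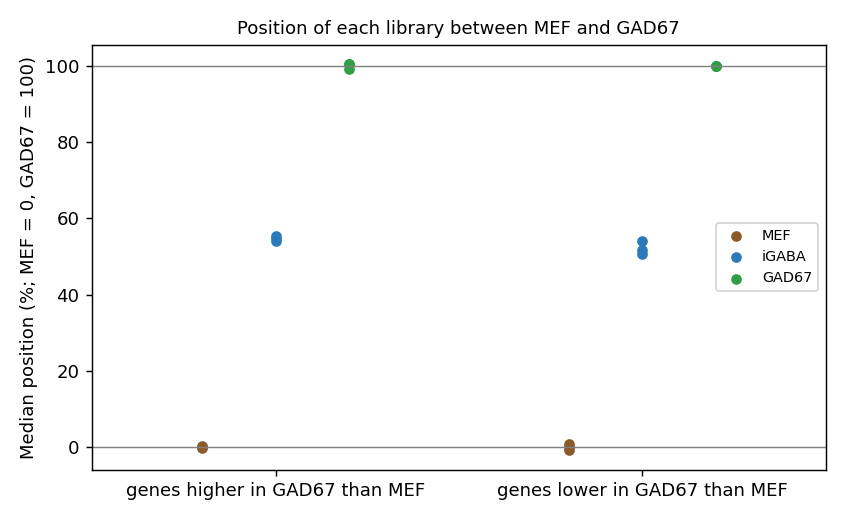
Median position of each library between the MEF mean (0%) and the GAD67 mean (100%) over genes at least 4-fold higher (left) or lower (right) in GAD67 than in MEF, with a point per library. The 3 iGABA libraries lie between 54.0% and 55.4% for the higher genes and between 50.8% and 54.1% for the lower genes.

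The changes from MEF to iGABA and from MEF to GAD67 correlated across 18085 genes with Pearson r of 0.69, against a mean of 0.50 in simulations with unchanged groups that share the MEF libraries, and the covariance was 6.00 against 0.0571. Genes higher in both numbered 5305, where independent lists would share 3286 and the simulations gave 0, and genes lower in both 5503, where independent lists would share 3147. The simulated value leaves out the changes of the groups and the independent-list value leaves out the shared MEF libraries, so part of either excess may come from those libraries. Genes that went opposite ways numbered 1351 higher in iGABA and lower in GAD67, and 1045 the other way. With the MEF libraries divided so that the changes shared no control library, a test chosen after the data were seen, mean r over 6 arrangements was 0.68 (0.677 to 0.686). Such a division removes the noise of shared libraries but not the shared fibroblast profile. How much of r comes from that profile was not tested.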

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

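Of 660.0 alternative values of summary results, for which a reversal was not scored, 626 stayed within their limit and 34 moved. Of 1862 for lists, 1755 kept direction and side of the threshold, 75 lost the call, 30 gained it and 2 reversed, and of 10968 for named genes, 10856 kept both, 22 lost the call, 84 gained it and 6 reversed. No paired analysis was possible because the labels give no replicate number that groups share. Depth limits genes near 0 counts, where folds are bounds.

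Testing against a 2-fold threshold (glmTreat), a stricter question by construction, left 3590 genes higher and 3695 lower for iGABA against MEF, 4567 and 5245 for GAD67 against MEF, and 4163 and 2980 for iGABA against GAD67. With an estimated correlation, 2 lists stayed higher and 1 lower for iGABA against MEF, 10 higher and 5 lower for GAD67 against MEF, and 2 higher and 3 lower for iGABA against GAD67. In the same order fry called 14 higher and 12 lower, 16 and 14, and 15 and 16. Fry does not compare a list with other genes, most of which were called, so its counts answer a different question from those of camera. Defining classes by a 2-fold difference, which admits more genes by construction, gave 5150 interneuron genes with 1035 within 2-fold of GAD67, and 5722 fibroblast genes with 781. Library size alone moved the median log2 fold change of all genes to 0.46, 0.22 and 0.22 in the 3 comparisons, as it leaves out the factors that centre it.

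The position of iGABA cells over interneuron genes was 53.9% with DESeq2 size factors, 63.5% with library size alone, 50.9% without a filter, 57.2% with a prior count of 0.5, and 52.7% to 54.8% leaving out 1 library. Over fibroblast genes it was 44.4% with library size alone, 56.1% without a filter, 49.9% with a prior count of 0.5, and 51.9% to 53.7% leaving out 1 library. Without a filter r was 0.67, and for these moves the cause was not tested.

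Directions reversed in fry for iGABA against GAD67 in proneural genes (median log2 fold change 0.67, fry adjusted p = 0.000187) and in astrocyte and radial glia genes (median -1.37, fry adjusted p = 2.95e-05), and the cause was not tested. Under library size alone log2 fold changes reversed for Gphn (0.32), Dpysl3 (0.40), Hoxd8 (0.37) and Aldoa (0.11) in iGABA against MEF, Cox5a (0.22) in GAD67 against MEF and Nnat (0.16) in iGABA against GAD67. Each moved with the median of all genes, which that scaling shifts by construction.

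Leaving out 1 library gave 7349 to 7897 genes higher and 6967 to 7439 lower for iGABA against MEF, 7650 to 7955 and 7713 to 7995 for GAD67 against MEF, and 7214 to 7495 and 6829 to 7292 for iGABA against GAD67.

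With DESeq2 in place of edgeR, lists were tested by limma's cameraPR, a form of camera that takes the DESeq2 statistic of each gene in place of log2 CPM. The list test thus changed together with the gene test. It no longer called cell cycle genes for iGABA against MEF (limma's cameraPR, adjusted p = 0.349, alternatives from 0.00303 to 0.750). It also lost subtype (0.0659), cell cycle (0.0905), glutamatergic (0.244), red blood cell (0.361), skeletal muscle (0.0841), keratinocyte (0.359) and oxidative phosphorylation genes (0.327) for GAD67 against MEF. For iGABA against GAD67 it lost glutamatergic (0.134), endothelial (0.398), red blood cell (0.298), keratinocyte (0.331) and oxidative phosphorylation genes (0.134). It gained presynaptic genes for iGABA against GAD67 (0.0314) and oligodendrocyte genes for iGABA against MEF (0.00149) and against GAD67 (0.00168), and the cause was not tested.

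Other settings ended or made calls of limma's camera as follows. Library size alone ended ion channels (adjusted p = 0.0593) and p53 genes (0.122) and made endothelial (0.0240) and oxidative phosphorylation genes (0.0240) for iGABA against MEF, ended oxidative phosphorylation genes (0.415) for GAD67 against MEF, and for iGABA against GAD67 ended keratinocyte (0.0907) and made subtype genes (0.0461). For iGABA against MEF, the CPM filter (0.0776) and thinning (0.0570) ended p53 genes, and no filter made postsynaptic genes (0.0373). Fitting only the libraries compared ended oxidative phosphorylation genes for GAD67 against MEF (0.0674). For iGABA against GAD67, endothelial genes were lost with the CPM filter (0.109), limma-voom (0.0777) and only the libraries compared (0.0581), within a range of 0.000768 to 0.573, and keratinocyte genes with limma-voom (0.0644). The cause was not tested.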

Other observations

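Genes chosen after their values were seen added to the picture of iGABA cells. Beside Pkd2l1, other genes known from spinal neurons that contact the cerebrospinal fluid did not move together. Gata2 stood at 49.4 ± 6.15 CPM in iGABA, 2.08 ± 0.0323 in MEF and 0.284 ± 0.0728 in GAD67 cells, and the myosin gene Myo3b at 14.4 ± 1.75, 0.0201 ± 0.0349 and 4.40 ± 0.726 CPM (SD, n = 3). Gata3 stood at 0.459 ± 0.0481 CPM in iGABA against 7.54 ± 0.616 in MEF cells, and Tal1 had no count in 3 iGABA libraries.

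Of 3 imprinted genes picked after their values were seen, Dlk1 stood at 6047 ± 102 CPM in iGABA and 1420.1 ± 69.1 in MEF cells, while Igf2 stood at 49.1 ± 11.6 against 15965 ± 876 CPM and H19 at 44.5 ± 9.02 against 12224 ± 645 CPM. Among mitochondrially encoded genes, mt-Cytb stood at 5783 ± 149 CPM in iGABA, 336 ± 30.3 in MEF and 2577 ± 334 in GAD67 cells, and mt-Rnr1, a ribosomal RNA, at 287 ± 6.86, 568 ± 45.4 and 225 ± 39.4 CPM. In the same order, mt-Rnr2 stood at 985 ± 19.01, 949 ± 39.6 and 842 ± 121 CPM and mt-Nd1 at 1655 ± 40.7, 585 ± 35.3 and 1700.2 ± 112 CPM. Far lower were mt-Co2, at 5.26, 1.15 and 2.41 CPM, mt-Co3, at 4.66, 1.13 and 2.19, and mt-Atp6, at 9.09, 1.56 and 2.66. Reads of genes with close nuclear copies could have been dropped, so levels of mitochondrial genes are uncertain. Xist, the RNA of the inactive X chromosome, read 404, 387 and 189 CPM in the MEF libraries, 1308, 1228 and 1287 in iGABA, and 415, 3.76 and 1043 in GAD67, and the labels used here give no sex. Levels as far apart as those of the GAD67 libraries argue against repeats of 1 RNA sample in that group. The other groups are left open.

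The tests of the 3 patterns that follow were chosen after the results were seen, and the counts over other splits of the libraries before. Trunk Hox genes were higher in iGABA than in GAD67 cells. RNA of leftover fibroblasts with the mean MEF profile would lower Hox and fibroblast genes alike. The median log2 fold changes of these lists from MEF were 1.22 and -6.24, a gap of 7.47 against a summed spread of 3.31. That counts against leftover fibroblasts of that profile as the source. Over the planned scalings of the libraries the lowest median was 10.07. Those scalings shift all genes by far less than that, so this could hardly have come out otherwise. Other kinds of scaling were not examined. A body position kept from the fibroblasts of origin is a hypothesis that these groups leave untested.

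Fibroblast genes higher in iGABA than in GAD67 cells could reflect a fixed share of unchanged fibroblasts. Of 32 such genes, 17 (53.1%) lay within 2-fold of their median share of the MEF level, 1.32%, which does not decide the question. In a test added after that result, 7 genes lay more than 4 times above that share beyond their error. They ran from Loxl1 at 10.3% to Pdgfra at 55.0% and Cd44 at 87.8%. That counts against a fixed share of fibroblasts with the mean MEF profile as the source of those 7. Leftover fibroblasts with another profile were not examined. Over the planned scalings the lowest median log2 fold change was 2.60. Those scalings shift all genes by less than that, and other kinds of scaling were not examined. Incomplete silencing in converted cells remains untested.

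GABA and ventral forebrain genes stood at unequal shares of their GAD67 level in iGABA cells. If a small share of cells carried the full interneuron profile, the genes would share a single percentage, but 6 of 27 (22.2%) lay within 2-fold of the median share of 4.20%, a figure that includes genes MEF cells express. In a test added for that reason, over 14 genes with a MEF level of at most 1% of GAD67 and with that level subtracted, 4 (28.6%) lay within 2-fold of the median share of 1.65%, with Prox1 at 56.5% and Nr2e1 at no count. That counts against such a mixture as the whole cause. Differences among genes within the converted cells, or from delivered Dlx5 and Lhx6, remain untested.

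Dividing the 6 libraries of a comparison in other ways gave 10 splits, and 1 of 10, the real split, reached the real count of called genes in each comparison. The real splits gave 14881, 15190.0 and 14147 genes in edgeR, and no other split gave more than 0, with at most 13, 15 and 33 genes at unadjusted p under 0.05. With 10 splits there are too few for a share under 0.05.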
